A study of Bacillus subtilis with 39 samples.

How the data were processed

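RNA from Bacillus subtilis 168 and from phoR-null, sigB-null and sigB phoR double-null mutants was profiled on 39 arrays around the transition to phosphate-limited growth. Per the labels, total RNA was copied into radioactively labelled cDNA, hybridised to Sigma-Genosys macroarrays and imaged on a Storm 860 PhosphorImager at 50 µm. Spots were quantified with background subtraction and the over-all-spot normalization of ArrayVision 5.1, duplicate spots were averaged, and gene lists were made in GeneSpring 4.2.12. Per the labels, each analysis used 2 RNA preparations and different array batches, and genes under a multiple of the background were not counted by the authors. The deposited values of 38 arrays are normalized intensity on a linear scale, scaled by the authors so that each array averages 1 (0.999 to 1.00). The remaining column, the wild type of series B at 2.75 h, is deposited as a ratio. Its mean was 1.42 and its median 1.05. Its product with the wild-type series B array at -1 h averaged 1.00, against 0.973 for the next closest array. It was read as a ratio to that array and left out of the fit, and 38 arrays were fitted.

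The table holds 4107 probes. Of these, 3862 map to 1 gene symbol, 32 to several and 213 to none, and 3848 symbols were found in the RefSeq gene table. Probes of the 13 symbols with several probes were averaged, which left 4094 features. Of 156066 values, 903 (0.579%) were at or below 0 (lowest -0.01) and were set missing. The medians of the arrays spanned 1.36 log2 units, above the limit of 0.5, so each array was centred on its median log2 value. Changes are therefore relative to the median gene. In the uncentred values the median of all genes moved by 0.18 in the wild type, -0.14 in the phoR-null strain, 0.14 in the double null, -0.28 in the phoR-null minus wild-type responses and -0.16 in the sigB-null minus wild-type responses. The shift was -0.21 for the phoR-null strain against the wild type after the transition and -0.22 for late against early wild-type arrays.

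Arrays before 0 h were called before, those from 0 h to under 1 h transition, and those from 1 h on after. Group means were fitted with limma 3.58.1 in R 4.3.3, with the 7 time series as a fixed block for changes within strains and for differences between strains in those changes. The strains were compared directly after the transition with series as a random block (statmod 1.5.0, correlation within series 0.611). A gene was tested where each group had a value on at least 2 arrays. Adjusted p-values are Benjamini-Hochberg values from limma with a threshold of 0.05. Time points of a series are treated as replicates by these p-values. Each series was taken as 1 culture and 1 array batch, which the labels do not state outright, least of all for the wild-type series without a letter. On that reading there are at most 2 cultures per strain and 1 for the double null, and culture and array batch cannot be separated.

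The 18 gene lists were fixed before the data were examined, as were the groups, comparisons and most alternatives. They cover the Pho regulon activated by PhoP, tag teichoic acid genes, the SigB general stress regulon, sporulation, ribosomal proteins, purine and pyrimidine synthesis, ATP synthase, glycolysis, the tricarboxylic acid cycle, terminal oxidases, motility, competence, surfactin, extracellular proteases, heat shock, the PBSX prophage and fatty acid synthesis. Lists were tested two-sided with camera at a preset correlation of 0.01 and again with an estimated correlation, on the 3680 genes with a value on every array. The direct strain comparisons used cameraPR with the preset correlation, on all genes tested. So did the list tests of single series, of the transition arrays, within an array family and with series as a random effect. P-values of lists were adjusted over the lists of a comparison. Named genes are the 10 highest and the 10 lowest changes past the threshold with the same sign in each series, a fixed set of Pho and SigB genes, and up to 4 members of each list with the largest change. Genes of that set without a named probe, among them pstS and tuaA, are left out. The gene of the phosphate-regulated glycerophosphodiesterase is given under its current symbol glpQA, and yvyD as hpf.

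The fit was tested on simulated data with 3680 genes. Normal noise was drawn independently for each array around its series mean, and a change was the same on every after array of a strain. Correlated time points, missing values and series that respond differently were not simulated, so the shares describe that setting and not these data. In the wild-type comparison 29.9% of genes changed by 1 log2 unit were recovered, 89.6% of those changed by 2 and 97% of those changed by 3, with 13 false calls among unchanged genes. For the phoR-null minus wild-type responses the shares were 13.4%, 65.7% and 84.8%, with 5 false calls. For arrays, their number limits the precision.

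Alternatives left out the series block, took 1 mean per series and phase, left values uncentred, used quantile normalization, dropped the dimmest 25% of genes, added a pseudocount of 0.0606 (percentile 5 of all values) or used series as a random effect. Further ones limited the after group to 1 to 3 h, counted transition arrays as after, used each series alone and left out each array. Chosen after the data were seen were the recovered ratio array, 4 array families (average linkage on Spearman correlation across genes) in the block or as the limit of the comparison, and rounding to 1 decimal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.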

Results

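Transcript levels were measured on 39 macroarrays of Bacillus subtilis sampled from -3 h to 8.5 h around the transition to phosphate-limited growth. Besides the wild type, there were mutants without phoR, the sensor kinase of the phosphate response, without sigB, the general stress sigma factor, and without both. The wild type has 3 arrays before, 2 at and 7 after the transition, 6 of which were fitted. The phoR-null strain has 4, 2 and 5, the sigB-null strain 2, 3 and 6, and the double null 2, 1 and 2. All but the double null were sampled in a pair of series, so that 7 series were available. Across genes, arrays of the same series had a median Spearman correlation of 0.83 over 85 pairs (0.52 to 0.97), and arrays of different families, groups formed by similarity, 0.50 over 521 pairs (0.28 to 0.82). Genes are not independent replicates in these correlations. The families follow the series rather than the strains: the unlettered wild-type series and phoR-null series A form 1 family, and wild-type series B, sigB-null series B and 4 double-null arrays another. Values below are normalized intensities per gene or their log2 changes with standard error (SE), and every adjusted p is from limma.

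The wild type after and before the transition was compared to see which genes change as growth becomes phosphate-limited. No culture without this transition was sampled, so culture age and growth phase cannot be told apart from phosphate limitation in any strain. The largest rise among all genes was that of phoB, an alkaline phosphatase gene of the Pho regulon, which is switched on by PhoR and its response regulator PhoP. Its intensity went from 0.224 ± 0.0923 (SD, n = 3) before to 14.9 ± 10.9 (SD, n = 6) after, a 53-fold change (log2 5.73 ± 0.45 SE, adjusted p = 1.6e-10), and all 6 after arrays (6.13 or more) lay above all before arrays (0.33 or less). The phosphatase gene phoA rose by 3.55 ± 0.58, the phosphodiesterase gene phoD by 3.37 ± 0.97, ydhF by 4.52 ± 0.49, the teichuronic acid synthesis gene tuaG by 3.62 ± 0.50, and the glycerophosphodiester phosphodiesterase gene glpQA by 2.27 ± 0.61. Of 17 measured Pho genes, 11 rose, none fell and 6 did not pass, with 13 rising when adjusted over the list alone. The median change was 2.27, and the list differed from the other genes (camera adjusted p = 3.5e-14, and 0.0063 with an estimated correlation). The regulator genes themselves did not pass, with phoP at 1.11 ± 0.59 and phoR at 0.55 ± 0.32. The tag genes for wall teichoic acid, a phosphate-rich polymer, were split: tagC rose (1.77 ± 0.43), tagD, tagH, tagE and tagA fell (-1.51, -1.37, -1.32 and -1.09), and 5 of 10 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.149).

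Genes of growth fell in the wild type. Of 50 ribosomal protein genes 38 fell, none rose and 12 did not pass, with 44 falling when adjusted over the list alone. Ribosomal protein genes as a list had a median change of -2.28 (camera adjusted p = 5.66e-35, and 0.0063 with an estimated correlation). Among them were rpsM (-3.78 ± 0.64), rpmJ (-3.72 ± 0.60) and rplR (-3.58 ± 0.58). Purine synthesis held the deepest fall of all genes, purH at -4.96 ± 0.41 (adjusted p = 4.71e-10, lower on all 6 after arrays than on all 3 before), followed by purF (-4.32 ± 0.45), purQ (-4.09 ± 0.47) and purN (-4.06 ± 0.43). In that list 9 of 16 genes fell and 7 did not pass, with 10 falling when adjusted over the list alone. Purine genes as a list had a median change of -1.34 (camera adjusted p = 8.75e-10, and 0.0063 with an estimated correlation). The NAD synthesis gene nadB (-3.99 ± 0.46) and the biotin synthesis gene bioW (-3.50 ± 0.38) fell too.

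Energy and lipid genes went the same way in smaller numbers. In ATP synthase 3 of 9 genes fell, 6 when adjusted over the list alone (atpC -1.76 ± 0.49). The ATP synthase list had a median change of -1.16 (camera adjusted p = 0.00321, adjusted p = 0.0848 with an estimated correlation). Glycolysis had 4 of 8 falling, 5 when adjusted over the list alone (pgk -1.46 ± 0.36, pyk -1.38 ± 0.34). Glycolysis genes had a median change of -1.34 (camera adjusted p = 0.00484, adjusted p = 0.196 with an estimated correlation). In the tricarboxylic acid cycle 2 of 10 fell, 3 when adjusted over the list alone (icd -1.82 ± 0.41). Genes of the cycle had a median change of -0.79 (camera adjusted p = 0.0389, adjusted p = 0.288 with an estimated correlation). Fatty acid synthesis had 2 of 10 falling, 4 when adjusted over the list alone (fabF -1.64 ± 0.37). Fatty acid genes had a median change of -0.81 (camera adjusted p = 0.0358, adjusted p = 0.231 with an estimated correlation).

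Stress and sporulation genes rose in part. Of 75 genes of the SigB regulon 10 rose, 1 fell and 64 did not pass, with 12 rising when adjusted over the list alone. The SigB list had a median change of 0.65 (camera adjusted p = 1.74e-07, adjusted p = 0.196 with an estimated correlation). The peroxide resistance gene ohrB rose by 3.23 ± 0.53, ywzA by 2.68 ± 0.61, and the catalase gene katE by 1.48 ± 0.47, while the starvation-induced gene gsiB, at 2.01 ± 0.68, missed the threshold (adjusted p = 0.0518). The sigB gene was at 0.77 ± 0.40, ctc at 0.59 ± 0.56, gspA at 0.95 ± 0.44 and hpf at 0.73 ± 0.73, none of which passed. Of 40 sporulation genes 14 rose, 1 fell and 25 did not pass, with 18 rising when adjusted over the list alone. The sporulation list had a median change of 1.21 (camera adjusted p = 2.82e-07, and 0.0481 with an estimated correlation). Among them were cotJA of the spore coat (3.29 ± 0.92), spoIVA, which anchors the coat (2.98 ± 0.55), and spoIIE (2.49 ± 0.58). Outside the lists, skfA of the sporulation killing factor operon rose by 5.55 ± 1.08, the oxalate decarboxylase gene oxdC by 3.94 ± 0.60 and the antiterminator gene sacT by 3.60 ± 0.70.

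The remaining lists did not pass camera in the wild type. Of the heat shock genes dnaK, dnaJ and grpE, chaperone genes of 1 operon, fell (-2.13 ± 0.40, -2.07 ± 0.43 and -1.80 ± 0.32), 3 of 14 also when adjusted over the list alone (camera adjusted p = 0.12). In the terminal oxidases 3 of 22 fell, 3 when adjusted over the list alone (qoxD -2.20 ± 0.45, camera adjusted p = 0.209), and in pyrimidine synthesis 2 of 8, 2 when adjusted over the list alone (pyrR -1.47 ± 0.48, camera adjusted p = 0.149). The protease gene bpr rose (1.64 ± 0.52), 1 of 8 in its list and 1 when adjusted over the list alone (camera adjusted p = 0.374). In motility flgL fell (-1.12 ± 0.28), 1 of 39 and 1 when adjusted over the list alone (camera adjusted p = 0.968). The phage gene xkdT fell (-1.28 ± 0.40), 1 of 30 PBSX genes and 0 when adjusted over the list alone (camera adjusted p = 0.593). None of the 18 competence genes or the 4 surfactin genes passed limma in either way of adjusting (camera adjusted p = 0.785 for each). For competence the median was 0.11 and the mean -0.04.

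In the wild type limma placed 127 genes higher and 331 lower of 4094 tested, 458 in all, 452 of them with the same sign in both series. The unlettered series alone gave 315 genes and series B, with a single before array, 83, and the Pho list had a median of 3.03 in the first and 1.45 in the second. The total was 208 without the unlettered before array at -0.5 h, 268 without the before array of series B, 219 with the after group limited to 1 to 3 h, 140 with 1 mean per series and phase, and 111 without the series block.

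**Figure D1:**
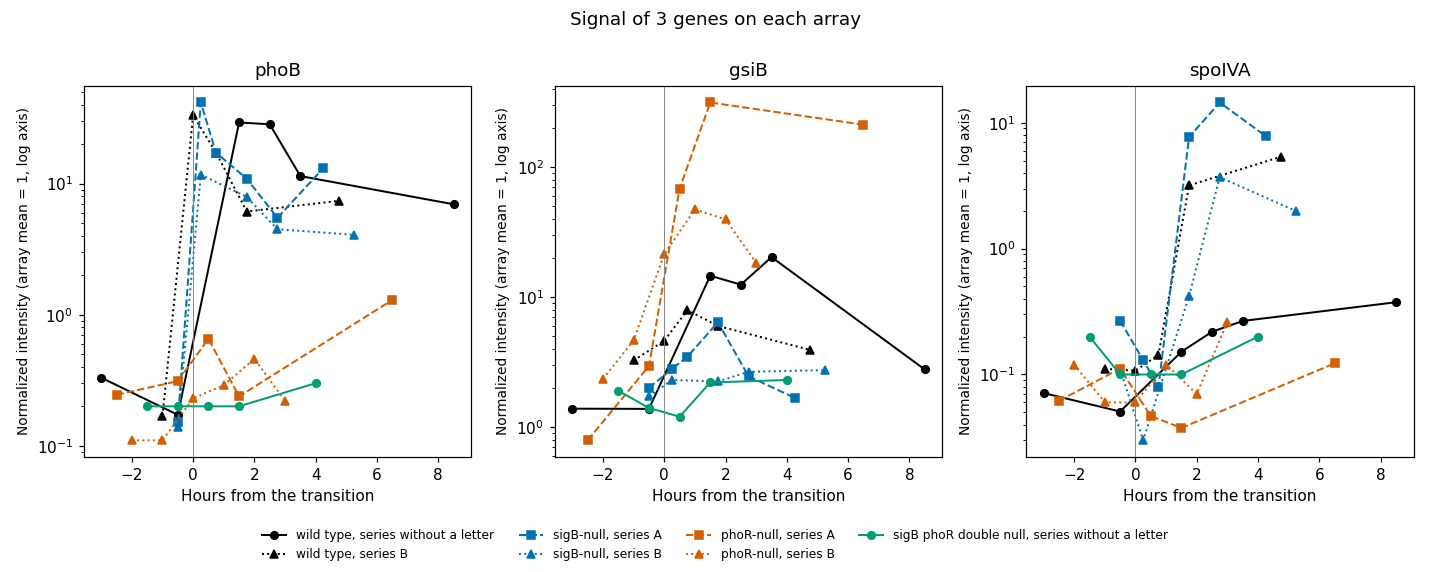
Normalized intensity (log axis) of phoB, gsiB and spoIVA on each array against hours from the transition, 1 line per series and 1 colour per strain. The phoB values lie at 6.13 or more on the wild-type after arrays and at 1.3 or less on all phoR-null arrays. In the phoR-null strain gsiB reaches 315.1, on the series A array at 1.5 h, against 20.32 in the wild type.

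The phoR-null strain was followed through the same transition to see what is left of the response without the kinase. Its strongest rise was in the SigB regulon. The stress gene gsiB rose 39.4-fold (5.30 ± 0.65, adjusted p = 8.36e-07), from 2.68 ± 1.59 (SD, n = 4) to 127 ± 131 (SD, n = 5), and was higher on all 5 after arrays than on all 4 before. The after arrays of series A held gsiB at 315.1 (1.5 h) and 212.6 (6.5 h), so the mean of 127 rests largely on that series. Of 75 SigB genes 43 rose, none fell and 32 did not pass, with 57 rising when adjusted over the list alone. The SigB list had a median change of 1.50 (camera adjusted p = 2.89e-32, and 0.00324 with an estimated correlation). Among them were ysnF (4.48 ± 0.52), ywzA (4.43 ± 0.58), csbD (3.83 ± 0.51), gspA (3.41 ± 0.42), hpf, a ribosome hibernation factor (2.81 ± 0.70), ctc (2.55 ± 0.54), katE (1.46 ± 0.45) and sigB itself (1.87 ± 0.38). Outside the list, nhaX (4.51 ± 0.42), lyxE (4.31 ± 0.55), sufLB (4.23 ± 0.58), ybyB (3.68 ± 0.54) and skfA (3.42 ± 1.03) rose. The list median was 2.34 in series A and 0.764 in series B.

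Of the Pho genes 1 of 17 rose, phoB by 1.40 ± 0.43 (adjusted p = 0.0281), and 1 fell, phoR (-1.38 ± 0.30, adjusted p = 0.00204). Adjusted over the list alone, 3 rose and 1 fell. With phoR set aside, the list median was 0.72 (camera adjusted p = 0.00257, adjusted p = 0.284 with an estimated correlation). Over all 17 genes the list median was 0.72 (camera adjusted p = 0.0173, adjusted p = 0.386 with an estimated correlation). That call ended without the array at 6.5 h, where the median was 0.49 (adjusted p = 0.0823), without the series B before array at -2 h (0.78, adjusted p = 0.0672), with the after group limited to 1 to 3 h and with transition arrays counted as after. Below the threshold stayed phoA at 0.72 ± 0.56, phoD at 1.49 ± 0.92, glpQA at 1.70 ± 0.58 and phoP at -0.15 ± 0.56. The phoR probe gave signal on the phoR-null arrays (0.199 to 1.49), and the labels do not say which part of the gene was disrupted.

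The fall of growth genes was seen here too. Of 50 ribosomal protein genes 43 fell, 45 when adjusted over the list alone (rplQ -3.86 ± 0.47, rplV -3.79 ± 0.47). Ribosomal protein genes had a median change of -2.49 (camera adjusted p = 2.53e-43, and 0.00324 with an estimated correlation). In purine synthesis 6 of 16 fell, 8 when adjusted over the list alone (purQ -3.81 ± 0.45). Purine genes had a median change of -0.79 (camera adjusted p = 0.000397, adjusted p = 0.107 with an estimated correlation). The quinolinate synthase gene nadA (-4.40 ± 0.79), the adenylate kinase gene adk (-3.63 ± 0.44) and the translation factor gene infC (-3.43 ± 0.63) also fell. In fatty acid synthesis 4 of 10 fell, 5 when adjusted over the list alone (accD -2.63 ± 0.60). Fatty acid genes had a median change of -1.02 (camera adjusted p = 0.0103, adjusted p = 0.185 with an estimated correlation). In motility 6 of 39 fell, 7 when adjusted over the list alone (fliT -1.36 ± 0.43). Motility genes had a median change of -0.58 (camera adjusted p = 0.00293, adjusted p = 0.185 with an estimated correlation). Pyrimidine synthesis had 2 of 8 falling, 4 when adjusted over the list alone (pyrE -2.03 ± 0.40). Pyrimidine genes had a median change of -0.94 (camera adjusted p = 0.0338, adjusted p = 0.319 with an estimated correlation). In ATP synthase 2 of 9 fell, 2 when adjusted over the list alone (atpC -2.63 ± 0.47). ATP synthase genes had a median change of -0.64 (camera adjusted p = 0.0298, adjusted p = 0.222 with an estimated correlation). Of 40 sporulation genes 2 rose, 1 when adjusted over the list alone (spoIIIAD 2.06 ± 0.54, spoIIIAC 1.19 ± 0.37). The change of spoIIIAD was higher in series A than in series B by 4.22 ± 0.74. Sporulation genes had a median change of 0.38 (camera adjusted p = 0.0723). None of the other 9 lists passed camera. Among them, 3 of 10 tag genes fell here too, 3 when adjusted over the list alone (median -0.76, camera adjusted p = 0.13). In limma 168 genes were higher and 293 lower of 4094 tested (461), with 513 in series A alone and 170 in series B alone, and with 114 taking 1 mean per series and phase and 123 without the series block.

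The sigB-null strain shows the response without the stress sigma factor. Its highest rises were skfA (6.83 ± 1.25) and phoB (5.68 ± 0.52, 51.2-fold, adjusted p = 8.61e-09, with 4.07 or more on all 6 after arrays and 0.151 or less on both before arrays). Of 17 Pho genes 11 rose, 12 when adjusted over the list alone (phoA 4.75 ± 0.67, glpQA 2.79 ± 0.71, phoP 2.50 ± 0.68, phoR 1.85 ± 0.37). The Pho list had a median change of 2.19 (camera adjusted p = 1.94e-14, and 0.0039 with an estimated correlation). Sporulation genes were among the top: cotJA rose by 5.51 ± 1.06, the forespore gene spoIIQ by 5.11 ± 0.68, spoIVA by 4.54 ± 0.64, spoIIIAH by 4.44 ± 0.80 and spoIIID by 4.33 ± 0.82. In that list 20 of 40 rose, 1 fell and 19 did not pass, with 24 rising when adjusted over the list alone. Sporulation genes as a list had a median change of 1.89 (camera adjusted p = 1.56e-14, and 0.0039 with an estimated correlation). Of 75 SigB genes 1 rose (yxaB, 1.43 ± 0.43) and 1 fell (nadE, -1.57 ± 0.49), 0 when adjusted over the list alone by limma, with a median of 0.08 (camera adjusted p = 0.416). The values of gsiB (0.66 ± 0.79), katE (0.42 ± 0.55) and sigB (-0.42 ± 0.46) did not pass.

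Growth genes fell in the sigB-null strain as well, 29 of 50 for ribosomal proteins and 40 when adjusted over the list alone (rpsF -3.50 ± 0.67). The ribosomal protein list had a median change of -2.14 (camera adjusted p = 9.29e-37, and 0.0039 with an estimated correlation). In purine synthesis 11 of 16 fell, 14 when adjusted over the list alone (purD -4.85 ± 0.57, purQ -4.74 ± 0.54). The purine list had a median change of -1.55 (camera adjusted p = 7.97e-17, and 0.000237 with an estimated correlation). Glycolysis had 3 of 8 falling, 3 when adjusted over the list alone (pgm -2.39 ± 0.62). Glycolysis genes had a median change of -0.74 (camera adjusted p = 0.00128, adjusted p = 0.158 with an estimated correlation). In pyrimidine synthesis 3 of 8 fell, 3 when adjusted over the list alone (pyrR -1.95 ± 0.56). Pyrimidine genes had a median change of -0.66 (camera adjusted p = 0.0101, adjusted p = 0.182 with an estimated correlation). No ATP synthase gene passed limma in either way of adjusting (median -0.57, camera adjusted p = 0.0271, adjusted p = 0.182 with an estimated correlation). None of the other 10 lists passed camera. Of their genes bpr (2.31 ± 0.60), vpr (2.06 ± 0.55), tagC (1.75 ± 0.50) and the chaperonin gene groEL (1.62 ± 0.46) rose, while qoxD (-1.81 ± 0.52), dnaK (-1.68 ± 0.47), grpE (-1.60 ± 0.37) and sdhC (-1.40 ± 0.36) fell. In limma 130 genes were higher and 126 lower of 4087 tested (256), with 295 in series A alone and 55 in series B alone. Leaving out the series A before array, the only 1 of that series, left 29 genes, and 133 were called with 1 mean per series and phase.

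In the double null neither the Pho list nor the SigB list passed. Of 16 Pho genes 0 passed limma, also adjusted over the list alone, with phoB at 0.13 ± 0.63 (intensity 0.2 on both before arrays, 0.25 ± 0.0707 SD after, n = 2). The Pho median was 0.13 (camera adjusted p = 0.592). Of 72 SigB genes yhdF fell (-2.66 ± 0.71), 1 also when adjusted over the list alone (median 0.04, camera adjusted p = 0.413), and none of 33 sporulation genes passed in either way of adjusting (median 0.19, camera adjusted p = 0.234). The ribosomal protein genes fell, 27 of 49 and 40 when adjusted over the list alone (rplNA -4.99 ± 0.80, rpsF -4.80 ± 0.82). The ribosomal protein list had a median change of -2.55 (camera adjusted p = 6.01e-43, and 0.00666 with an estimated correlation). Purine genes fell in 4 of 14 cases, 6 when adjusted over the list alone (purH -4.49 ± 0.58). The purine list had a median change of -0.87 (camera adjusted p = 1.73e-06, and 0.0261 with an estimated correlation). Glycolysis had 1 of 8 falling, 3 when adjusted over the list alone (pyk -2.32 ± 0.48). Glycolysis genes had a median change of -1.49 (camera adjusted p = 0.00143, adjusted p = 0.231 with an estimated correlation). In ATP synthase 1 of 9 fell (atpD), 1 when adjusted over the list alone. ATP synthase genes had a median change of -0.66 (camera adjusted p = 0.0399, adjusted p = 0.326 with an estimated correlation). No motility gene of 37 passed limma in either way of adjusting (median -0.43, camera adjusted p = 0.0164, adjusted p = 0.336 with an estimated correlation), and the other 10 lists did not pass camera. The siroheme synthesis gene sirB fell (-4.87 ± 1.08). The 5 genes that rose were the sporulation phosphatase gene rapA (3.93 ± 0.81), murP (3.31 ± 0.86), ytzD, yueH and sdpA. In limma 5 genes were higher and 81 lower of 3796 tested (86; 508 at an unadjusted p under 0.05). Values of this strain were deposited to 1 decimal, and 54 to 175 per array were at or below 0 and set missing. With 2 before and 2 after arrays a gene needed a value on each of them. Genes near the floor, including any that rise from it, were therefore left untested, and 33 of 40 sporulation genes remained. Of the before arrays, that at -1.5 h falls in the array family of phoR-null series B, apart from its own series. The count was 556 without the other before array, 23 without this one, 21 and 34 without either after array in turn, and 9 with 1 mean per series and phase. Rises made up 5.81% of the calls and 57.8% with a pseudocount.

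**Figure D2:**
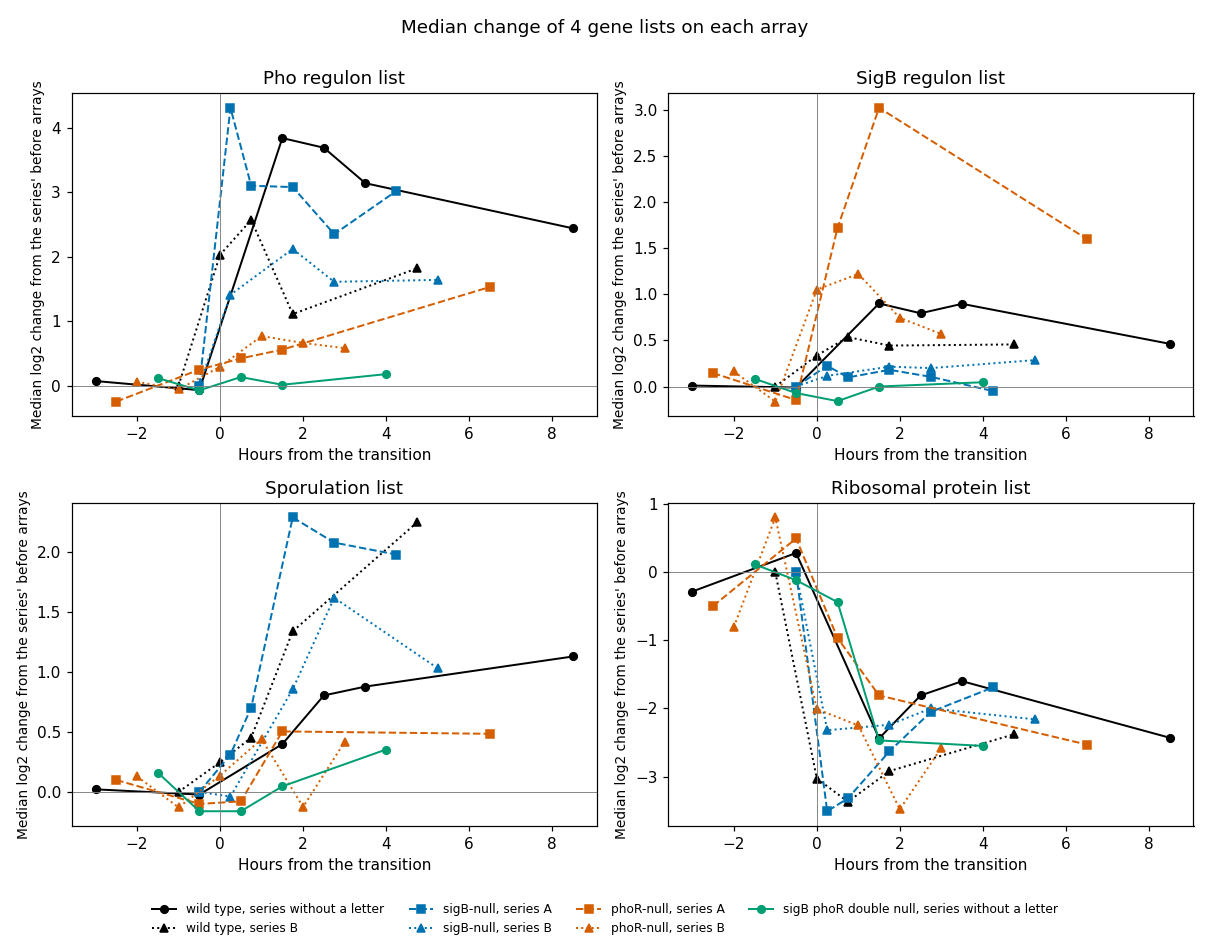
Median log2 change of the genes of 4 lists from the before arrays of the same series, per array, against hours from the transition. The Pho list stands between 1.11 and 3.84 on the wild-type after arrays and at or below 0.178 on the double-null arrays, and the SigB list reaches 3.02 in series A of the phoR-null strain.

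The responses of the phoR-null strain and the wild type were subtracted to ask which changes depend on the kinase. The change of phoB was lower in the mutant by -4.33 ± 0.62 (adjusted p = 0.000121), and those of ydhF (-3.58 ± 0.67), tuaF of teichuronic acid synthesis (-2.92 ± 0.57), rplS (-2.98 ± 0.71), ywcI (-2.93 ± 0.67), ysfB (-1.87 ± 0.43), phoR (-1.93 ± 0.44) and 4 probes without a gene entry were lower too. Of 17 Pho genes 4 had a lower change, 7 when adjusted over the list alone, and all 17 estimates were negative (median -1.69, camera adjusted p = 3.43e-11, and 0.0462 with an estimated correlation). The count includes phoR, the gene disrupted in this strain. With phoR set aside, 3 of 16 had a lower change, 6 when adjusted over the list alone (median -1.52, camera adjusted p = 1.15e-09, adjusted p = 0.114 with an estimated correlation). The difference for phoA, -2.83 ± 0.81, did not pass (adjusted p = 0.14). Higher in the mutant were the changes of ysnF (3.78 ± 0.75), the prophage gene yopP (3.74 ± 0.51), ycbP (3.50 ± 0.67), the efflux regulator gene bmrR (3.34 ± 0.51), csbD (3.27 ± 0.74) and nhaX (2.49 ± 0.61). Of 75 SigB genes 3 had a higher change, 7 when adjusted over the list alone (median 0.77, camera adjusted p = 1.48e-11, adjusted p = 0.151 with an estimated correlation), while gsiB (3.29 ± 0.94, adjusted p = 0.14) and gspA (2.46 ± 0.61, adjusted p = 0.0522) did not pass. The SigB difference was larger with phoR-null series A alone (1.43, adjusted p = 6.43e-20) than with series B alone (0.23, adjusted p = 0.0163), and the change of the list in series B (0.764) was below that in the unlettered wild-type series (0.837).

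The purine genes purH (3.08 ± 0.57) and purF (2.94 ± 0.63) and the NAD salvage gene pncB (2.85 ± 0.53) had higher changes in the phoR-null strain. Of the purine genes 2 of 16 differed, 3 when adjusted over the list alone (median 0.64, camera adjusted p = 0.000811, adjusted p = 0.151 with an estimated correlation), and the list median was -0.03 (adjusted p = 0.562) with phoR-null series A alone and 0.23 (adjusted p = 0.391) within the shared array family. No sporulation gene of 40 passed limma in either way of adjusting, with spoIVA at -2.65 ± 0.76 (median -0.82, camera adjusted p = 0.000667, adjusted p = 0.208 with an estimated correlation). That call ended with after limited to 1 to 3 h (-0.52, adjusted p = 0.0967) and within the array family that phoR-null series A shares with the unlettered wild-type series (-0.40, adjusted p = 0.356). No gene of motility passed across all genes, 1 was lower when adjusted over the list alone (median -0.52, camera adjusted p = 0.000917, adjusted p = 0.17 with an estimated correlation), and none of the tricarboxylic acid cycle passed (median 0.82, camera adjusted p = 0.0113, adjusted p = 0.254 with an estimated correlation). For ribosomal proteins 1 of 50 differed (rplS), 1 when adjusted over the list alone. The ribosomal protein list had a median difference of -0.19 (camera adjusted p = 0.233). Of 10 tag genes none differed in either way of adjusting (median -0.38, camera adjusted p = 0.978). In limma 14 genes had a higher and 11 a lower change in the mutant of 4094 tested (25; 398 at an unadjusted p under 0.05). With before and after redrawn within each strain but across its series, as planned, 2 of 95 splits, the real one included, gave as many genes. Redrawn within each series, a choice made after the results were seen, 6 of 100 did. Without single arrays the count was 6 (wild type before, -0.5 h), 11 (phoR-null after, series A, 1.5 h) to 33, it was 1 with 1 mean per series and phase, 61 within the shared array family, and the share of higher changes was 56%, or 35.3% in uncentred values.

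Against the wild-type response, the sigB-null response differed for 0 genes by limma (338 of 4087 at an unadjusted p under 0.05). The SigB list had lower changes as a group (median -0.47, camera adjusted p = 1.51e-05, adjusted p = 0.675 with an estimated correlation), with 0 genes past the threshold and 4 when adjusted over the list alone, among them ohrB at -3.01 ± 0.80 and yflT at -3.90 ± 1.09. The sporulation list had higher changes as a group (median 0.48, camera adjusted p = 0.0301, adjusted p = 0.675 with an estimated correlation), with spoIIQ at 2.98 ± 0.90, as had heat shock (0.50, camera adjusted p = 0.0409, adjusted p = 0.675 with an estimated correlation). The Pho list did not pass (median -0.41, camera adjusted p = 0.606), with phoB at -0.05 ± 0.68. Without the sigB-null before array of series B 27 genes passed.

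The double-null response had a lower change than that of the wild type for 4 features (of 3796; 355 at an unadjusted p under 0.05): phoB (-5.60 ± 0.77, adjusted p = 0.000122), ydhF (-4.39 ± 0.85), tuaC (-4.07 ± 0.77) and a probe without a gene entry (-4.74 ± 1.01). Of 16 Pho genes 3 were lower, 7 when adjusted over the list alone. The Pho list had a median difference of -1.82 (camera adjusted p = 3.6e-11, and 0.0415 with an estimated correlation), or -2.18 with phoR set aside (camera adjusted p = 1.65e-11, adjusted p = 0.0513 with an estimated correlation). No gene of the SigB list (median -0.45, camera adjusted p = 0.00174, adjusted p = 0.749 with an estimated correlation), of sporulation (-0.72, camera adjusted p = 0.00388, adjusted p = 0.653 with an estimated correlation) or of motility (-0.66, camera adjusted p = 0.0252, adjusted p = 0.653 with an estimated correlation) passed limma in either way of adjusting. The count was 0 within the shared array family, 1 without the wild-type before array at -0.5 h, and 354 without the double-null before array at -0.5 h.

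Compared directly after the transition, the phoR-null strain and the wild type differed for 0 genes by limma (172 of 4094 at an unadjusted p under 0.05), with phoB at -4.48 ± 0.89 (adjusted p = 0.0645). As groups, with cameraPR, Pho genes were lower in the mutant (median -1.92, adjusted p = 4.37e-11, 4 genes lower when adjusted over the list alone), sporulation genes lower (-0.81, adjusted p = 0.000301), ribosomal protein genes lower (-0.85, adjusted p = 5.58e-05) and SigB genes higher (1.19, adjusted p = 2.92e-12). In the sigB-null strain against the wild type 0 genes passed limma (120 of 4094 at an unadjusted p under 0.05), while SigB genes were lower as a group (-0.52, adjusted p = 0.000115), ribosomal protein genes lower (-0.81, adjusted p = 8.72e-07) and sporulation genes higher (0.62, adjusted p = 0.00507). These list tests used the preset correlation alone. The phoR-null count was 99 without the series block, 143 with array families in it and 423 within the shared family. The last sets 1 series of each strain against the other without a series block, so an offset between the series is counted as strain. Each strain has 2 series here, and culture and array batch cannot be separated.

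Late (over 3 h) and early (1 to 3 h) wild-type arrays, 3 of each, differed for 0 genes by limma (145 of 4093 at an unadjusted p under 0.05). Sporulation genes were higher late as a group (median 0.55, camera adjusted p = 4.36e-11, and 0.00967 with an estimated correlation), and 5 of 40 were higher when adjusted over the list alone. The largest estimates were sspE, a spore protein gene (3.61 ± 1.09), cotJA (3.19 ± 0.91), spoIIID (2.28 ± 0.73) and the coat gene cotE (2.11 ± 0.59), none past the threshold over all genes. Ribosomal protein genes (median 0.21, camera adjusted p = 0.00842, adjusted p = 0.785 with an estimated correlation) and pyrimidine genes (-0.57, camera adjusted p = 0.00687, adjusted p = 0.287 with an estimated correlation) differed as groups, with 2 pyrimidine genes lower when adjusted over the list alone.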

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

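The tests of explanations below, the comparison within array families, the Pho list without phoR, and the splits within series or of whole series were chosen only after the results were seen; the counts over splits of all arrays and the limit to 1 to 3 h were planned before the data were examined.

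In the phoR-null strain the response of series A minus that of series B differed for 87 genes (53 higher in A and 34 lower; 607 at an unadjusted p under 0.05), among them bdbA (5.33 ± 0.75 SE) and the SigB gene ctc (4.27 ± 0.76), and the SigB list rose more in A (median 2.34) than in B (0.764). Arrays of series B that read out smaller changes stay open. The ribosomal protein list fell 1.32 times as far in B as in A. The lower limit of that difference was 0.215 log2 units, resampled over genes and not over arrays or cultures. Motility also changed more in B (median -0.65, against -0.476 in A), as did fatty acid synthesis (-1.12, -0.75). Purine synthesis changed less in B (-0.484, against -1.29), as did pyrimidine synthesis (-0.421, -1.38), Pho (0.544, 1.04) and sporulation (0.25, 0.522). The lists therefore do not decide it. Values at like or earlier times go against later sampling in A, but they rest on single arrays, so it is not excluded. The SigB list at 1.5 h in A stood 1.8 above the higher of the 1 h and 2 h values of B, which differ by 0.476. This is 1 array, and its median intensity stood apart from its group. At 0.5 h in A, again on 1 array, the list median already stood at 1.72. In B it was 1.05 at 0 h and 0.764 after the transition. Whether SigB genes were raised already before the transition in B stays open. The list stood 0.103 above the double-null array of the same family, against a gap of 1.58 between the series. That is less than this explanation alone would need. But it is 1 array, and the value says nothing if that array is mislabelled, which stays open below. A difference between the cultures, which the labels do not describe, stays open and was not tested.

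The sporulation list rose less in the phoR-null strain than in the wild type (median difference -0.825, camera adjusted p = 0.000667, adjusted p = 0.208 with an estimated correlation). A dependence of sporulation on phoR is the biological explanation that the design gives. Wild-type arrays later than 3 h could account for part of it: with after limited to 1 to 3 h the difference was -0.521 (adjusted p = 0.0967). Different array families could do so as well: within the shared family it was -0.401 (adjusted p = 0.356). Both values keep the direction and miss the threshold, so neither explanation can be told apart from an effect of phoR here. The shared family leaves out series B of both strains, so its smaller difference cannot be assigned to array families. In the wild type the list median was 1.8 in series B and 0.885 in the unlettered series. In the phoR-null strain it was 0.25 in series B and 0.522 in series A. Without the only before array of wild-type series B the difference was -0.338, with both phoR-null series still included.

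The double-null array at -1.5 h had Spearman correlations across genes of 0.516 to 0.577 with its own series and 0.712 to 0.889 with phoR-null series B. An array batch shared with that series may account for it: its difference from the next double-null array followed the difference between the families (Spearman 0.673), but RNA of the phoR-null strain would give the same. Against phoR-null RNA speaks that sigB stood at -1 on this array, below the range of phoR-null series B (-0.0418 to 1.71), but 1 gene on 1 array deposited to 1 decimal does not decide it. The array stays in the group its label gives, and no biological explanation was tested.

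Single arrays stood apart from their group in 6 of 76 tests, each of 1 array measure, gene or list in 1 group of arrays. The tests used the gap to the nearest array over the range of the group, with Dixon's limits at 0.05. Chance alone flags about 1 in 20 independent groups (4.86% to 5.25% of simulated groups of normal values of these sizes). The tests here share arrays, and a group holds different time points, so this rate is only a rough guide. List values are changes from the mean of the before arrays of the same series. The list tests of the phoR-null before group, counted among the 76, could therefore flag no array. The median deposited intensity of the phoR-null array at 1.5 h was 0.23, with the nearest of its group at 0.33. On the sigB-null array of series B at 2.75 h phoD stood at -3.49 relative to the array median, with the nearest at 1.76. For gsiB the sigB-null array of series A at 1.75 h stood at 4.9, with the nearest at 2.92. For hpf the wild-type array of series B at 1.75 h stood at -0.0447, with the nearest at 2.55. The Pho list stood at 1.53 on the phoR-null array at 6.5 h, with the nearest at 0.768. The Sporulation list stood at -0.125 on the phoR-null array of series B at 2 h, with the nearest at 0.417.

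Responses differed between strains by the test of the difference for 25 genes between the phoR-null strain and the wild type and for 4 between the double null and the wild type. As lists at the preset correlation, the phoR-null strain differed from the wild type for Pho (-1.69), SigB (0.769), purine synthesis (0.642), motility (-0.52) and the tricarboxylic acid cycle (0.822), besides sporulation. Of these Pho also passed with an estimated correlation (adjusted p = 0.0462), though not with the disrupted gene phoR set aside (-1.52, adjusted p = 0.114 with an estimated correlation), and the others did not (adjusted p = 0.151 for SigB and for purine synthesis, 0.17 for motility and 0.254 for the cycle, each with an estimated correlation). The sigB-null strain differed for SigB (-0.472), sporulation (0.478) and heat shock (0.495), none of which passed with an estimated correlation (adjusted p = 0.675 for each). The double null differed for Pho (-1.82), SigB (-0.453), sporulation (-0.718) and motility (-0.66). With an estimated correlation Pho passed (adjusted p = 0.0415), though not with phoR set aside (adjusted p = 0.0513), and SigB (adjusted p = 0.749), sporulation and motility (adjusted p = 0.653 for each) did not. Between the sigB-null series 7 genes differed (4 higher in series A and 3 lower; 441 at an unadjusted p under 0.05), and between the wild-type series 0 by limma (190 at an unadjusted p under 0.05).

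The ratio column of the wild type in series B at 2.75 h, not used in the fit, held a Pho list median of 0.956 and a Sporulation list median of 1.74 (log2, centred). Its highest ratios were those of spoIVA (71), spoIIQ (56.4), phoB (52.1) and skfA (52.1).

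Other splits of the arrays were counted for 6 results. For the wild type 1 of 83 splits, the real one, gave as many as the 458 genes, and the highest other gave 45. For the phoR-null strain 1 of 100 gave as many as 461, with 377 as the highest other. For the difference between these responses 2 of 95 splits gave as many as 25, with 27 as the highest other. These splits move arrays across series. With before and after redrawn only within each series, 1 of 45 splits gave as many genes in the wild type (highest other 23), 1 of 60 in the phoR-null strain (highest other 377) and 6 of 100 for the difference between the responses (highest other 341). Within series, only the real assignment of time points reached the counts of the wild type and the phoR-null strain. Other assignments reached the count of the difference. Time points of a culture are ordered and cannot be freely exchanged, so these shares do not exclude chance for any of the counts. The split with 341 genes, many times the real 25, points to a structure of the samples: it kept the labels of all 9 phoR-null arrays and of 3 of the 9 wild-type arrays. A response left whole in 1 strain then enters the difference, so these splits do not tell whether the responses differ by chance. Whole series exchanged between the strains make 3 splits, too few for a share under 0.05; the real one alone (1 of 3) gave as many as 25, and the highest other gave 2. For the direct comparisons after the transition all 100 splits gave as many as the 0 genes of the phoR-null strain, with 11 as the highest other, and all 100 as many as the 0 of the sigB-null strain, with 9 as the highest other; a count of 0 is reached by every split, so these say nothing about chance. For late against early wild-type arrays there are 10 splits, too few for a share under 0.05; the real value was 0 and the highest other 1.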

How the results depend on the processing

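Settings that use array families, the recovered ratio array, rounding or the Pho list without phoR were chosen only after the results were seen; the others were planned. The list medians followed through these settings (Pho, SigB, sporulation, ribosomal proteins and purine synthesis, in the comparisons where they lead) kept direction and call where not named here. Of 114 named gene changes, 2744 values under the settings kept the call in 2297 cases, lost it in 447 and turned direction in 0. The highest and lowest named changes were chosen for having the same sign in each series. For them that choice ruled out a turn of direction with 1 series alone and made it less likely elsewhere. The 0 turns are therefore no independent test of direction. The cause was not tested for any value below, except that 1 mean per series or 1 series alone leaves fewer arrays. Signal near background limits dim genes, and the double null was deposited to 1 decimal. All planned settings were run.

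Without the series block the genes past the threshold numbered 111 in the wild type (458 as reported), 123 in the phoR-null strain (461), 55 in the sigB-null strain (256), 4 in the double null (86), 2 for the phoR-null minus wild-type responses (25), 0 for the double-null minus wild-type responses (4), 99 for the phoR-null strain against the wild type after the transition (0) and 3 for the sigB-null strain against it (0). In the same order, 1 mean per series and phase gave 140, 114, 133, 9, 1 and 1 for the first 6, and 7 for late against early wild type (0). Uncentred values gave 55 in the double null and 1 for the phoR-null strain against the wild type, quantile normalization 137 and 1. For late against early, 3 genes passed without the dimmest genes and 2 with a pseudocount, which gave 223 in the double null.

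With after limited to 1 to 3 h the counts were 219 in the wild type, 34 in the double null, 15 for the phoR-null minus wild-type responses and 1 for the phoR-null strain against the wild type. The Pho list of the phoR-null strain (0.718) was then 0.486 (adjusted p = 0.0814), and the sporulation difference between the responses -0.521. With transition arrays as after the counts were 170 in the sigB-null strain, 5 in the double null, 1 for the sigB-null and 7 for the double-null minus wild-type responses and 5 for late against early, and the Pho list of the phoR-null strain was 0.578 (adjusted p = 0.0501). The recovered ratio array gave 1 for the phoR-null strain against the wild type and 2 for late against early. Array families in the block gave 23 in the double null, 143 for the phoR-null and 1 for the sigB-null strain against the wild type. Rounding gave 1 for the sigB-null minus wild-type responses and 1 for the phoR-null strain against the wild type.

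Series B alone gave 83 genes in the wild type, 170 in the phoR-null strain, with the Pho list at 0.544 (adjusted p = 0.055), and 55 in the sigB-null strain. The phoR-null minus wild-type responses gave 101 with phoR-null series A, 14 with phoR-null B and 3 with wild-type B, and their purine list turned direction with phoR-null A (-0.0313, adjusted p = 0.562) and was 0.343 (adjusted p = 0.0787) with wild-type B. The sigB-null minus wild-type responses gave 32 with sigB-null A, 3 with sigB-null B and 17 with the unlettered wild type, and those of the double null 14 with the unlettered wild type and 7 with wild-type B. After the transition the phoR-null strain differed from the wild type by 573 genes with phoR-null A, 1913 with phoR-null B, 1294 with the unlettered wild type and 734 with wild-type B. The sigB-null strain differed by 1835 with A, 57 with B, 1651 with the unlettered wild type and 200 with wild-type B. These direct comparisons, like those within the shared family, hold no series block. Time points then count as replicates, and an offset between cultures or array batches is counted as strain. With series as a random block the count was 0 for each strain. Late against early gave 2 with wild-type B. Within the shared family the counts were 61 for the phoR-null, 1 for the sigB-null and 0 for the double-null minus wild-type responses, and 423 and 2 for the phoR-null and sigB-null strains against the wild type, with the sporulation difference at -0.401 and the purine difference at 0.234 (adjusted p = 0.391).

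Leaving out 1 array at a time gave 208 to 445 genes in the wild type (208 without before at -0.5 h, 268 without before of series B), 309 to 605 in the phoR-null strain, 29 to 261 in the sigB-null strain (29 without before of series A) and 21 to 556 in the double null (23 without before at -1.5 h, 556 without before at -0.5 h, 21 and 34 without after at 1.5 h and 4 h). A lone array left in a group is assumed to vary like the other groups. The phoR-null minus wild-type responses gave 6 to 33: 6, 16, 16 and 15 without wild-type arrays of the unlettered series at -0.5, -3, 3.5 and 8.5 h, and 12, 13 and 11 without phoR-null series A at -0.5, -2.5 and 1.5 h. The sigB-null minus wild-type responses gave 0 to 27: 27 and 4 without sigB-null before of series B and A, 6 without wild-type before of series B, 5 without wild type at 4.75 h and 1 without sigB-null A at 2.75 h. Those of the double null gave 1 to 354: 354, 1 and 1 without double null at -0.5, 1.5 and 4 h, and 2, 1 and 8 without wild-type before at -3, -0.5 and -1 h. The phoR-null strain against the wild type gave 0 to 1 (1 without wild type at 8.5 h or phoR-null at 6.5 or 3 h), and the sigB-null strain 0 throughout. Late against early gave 0 to 6 (1 and 6 without wild type at 2.5 and 3.5 h). The Pho list of the phoR-null strain gave 0.486 to 0.857, without its call when the array at 6.5 h (adjusted p = 0.0823) or that at -2 h (0.782, adjusted p = 0.0672) was out.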

Other observations

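The tests of hypotheses here, including the contrasts of the double null with the single mutants and those that pool strains, were chosen only after the results were seen. The phoR effect with sigB is the difference between the phoR-null and wild-type responses, which was a planned comparison.

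The transition arrays (0 h to under 1 h), which belong to no comparison of the report, were compared with the before arrays of their own series; where a phase of a series has 1 array, limma assumes that it varies like the other groups. List tests used cameraPR with the preset correlation alone, on all genes tested, and the camera p-values given for these arrays are of this kind. No difference between strains or phases was tested for these arrays. In wild-type series B (2 arrays) limma placed 17 genes higher and 87 lower, with phoB at 7.26 ± 0.81 SE, phoA at 4.78 ± 0.79, the protease gene bpr at 3.16 ± 0.63, rplV at -6.29 ± 0.80 and purH at -5.29 ± 0.74. The Pho list median was 2.29 there and 1.45 after the transition, and the ribosomal protein list stood at -3.19 and then -2.74. In sigB-null series A (2 arrays) 79 genes were higher and 110 lower, among them phoA (7.66 ± 0.79), phoD (6.53 ± 1.49), glpQA (5.93 ± 0.78) and the protease gene vpr (4.43 ± 0.69). Its Pho list median was 3.73 and then 2.87. In sigB-null series B (1 array) 16 were higher and 21 lower, with phoB at 6.42 ± 0.94, and the Pho list stood at 1.41 and then 1.89. The sporulation list was already higher as a group in wild-type series B (median 0.44, camera adjusted p = 0.0411) and in sigB-null series A (0.49, camera adjusted p = 0.0197), but not in sigB-null series B (-0.04, camera adjusted p = 0.986).

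In the phoR-null strain the transition arrays held raised SigB genes. In series A (1 array) 38 genes were higher and 20 lower, with gsiB at 5.55 ± 0.93, ywzA at 5.18 ± 0.86, ctc at 3.97 ± 0.69, sigB at 2.42 ± 0.57 and its regulators rsbV (3.29 ± 0.67) and rsbW (3.20 ± 0.74). In series B (1 array) 20 were higher and 60 lower, with hpf at 4.41 ± 1.17, csbD at 3.95 ± 0.92 and ohrB at 3.87 ± 0.88. The SigB list median was 1.72 in series A (camera adjusted p = 2.05e-32) and 1.05 in series B (camera adjusted p = 4.12e-15), and the list was higher in wild-type series B as well (0.41, camera adjusted p = 0.0411). On the double-null transition array 0 genes passed limma (187 at an unadjusted p under 0.05), with the SigB list at -0.16 (camera adjusted p = 0.546) and the ribosomal protein list at -0.44 (camera adjusted p = 0.181). Of the 18 lists only purine synthesis passed there, lower (-0.77, camera adjusted p = 0.00338).

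The double-null response minus that of the phoR-null strain, an effect of sigB where phoR is absent, was lower for 13 genes and higher for 0 (430 at an unadjusted p under 0.05). Among them were sufLB (-5.18 ± 1.03), gsiB (-5.00 ± 1.16), ywzA (-4.59 ± 1.04), nhaX (-4.17 ± 0.75), gspA (-3.74 ± 0.75), bmrR (-3.67 ± 0.62) and yopP (-3.57 ± 0.64). The SigB list median was -1.61 (camera adjusted p = 1.97e-18, adjusted p = 0.0812 with an estimated correlation). A hypothesis is that the effect of phoR disruption on the SigB list may need sigB. The effect was 0.865 higher with sigB than without (camera adjusted p = 0.000341, adjusted p = 0.962 with an estimated correlation), and 0 genes passed the same contrast by limma (320 at an unadjusted p under 0.05), so the test leaves it open. The double null has 1 series, and 4 of its 5 arrays are in another array family than the phoR-null arrays.

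The double-null response minus that of the sigB-null strain was lower for 8 genes, among them spoIIQ (-5.77 ± 1.08), phoB (-5.55 ± 0.81), spoIVA (-4.70 ± 1.01) and sppO (-4.30 ± 0.94). A hypothesis is that sporulation genes may rise more where phoR is intact, with or without sigB. The strains with phoR minus those without gave a list median of 1.07 (camera adjusted p = 1.58e-08, and 0.0438 with an estimated correlation), with 37 genes past the threshold, 35 of them higher, including phoB (4.94 ± 0.51), spoIVA (3.67 ± 0.63) and spoIIQ (3.59 ± 0.68). This contrast pools both backgrounds. Taken apart, the phoR effect on the list was -0.825 with sigB (adjusted p = 0.208 with an estimated correlation; none of 40 genes passed) and -1.24 without (adjusted p = 0.118 with an estimated correlation), so the hypothesis stays open for each background. Array families and sampling times, which differ between these strains, stay open as well.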
